A study of Mus musculus with 4 samples.

How the data were processed

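Single-cell RNA was measured in 4 libraries of kidney cells from BAC-CluGFP mice, 1 library per group: untreated kidneys, and kidneys taken 2, 7 and 30 days after 35 min of ischemia followed by reperfusion (ischemia-reperfusion injury, IRI). Per the labels, kidneys were digested enzymatically and cells that carried green fluorescent protein (GFP) were collected by flow sorting before 10x Genomics droplet capture with 3′ chemistry. The number of animals behind each library is not given in the sources used here. With 1 library per group there was no spread between replicates, so no test was run and no p-value is given.

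The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, whole numbers with no normalization. Per the submitters' processing notes, Cell Ranger 7.0.1 and the mouse build mm10 were used, whereas the matrix headers carry the software version 3.0.1. The annotation release and the rule that kept barcodes are not given in the sources used here. Each library had its own lowest UMI total: 2335 UMIs in the untreated library, 3881 at day 2, 18362 at day 7 and 5976 at day 30. The matrices had 0 rows for GFP, so the reporter's own transcript was not analysed here. Gene coordinates came from a GENCODE annotation of the same mouse build.

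Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 50% of UMIs from mitochondrially encoded genes. The minimum on genes removed 1 barcode each from the untreated and day 2 libraries. The mitochondrial limit removed 2740 barcodes (29.5%) of the untreated library, 35 at day 2, 0 at day 7 and 45 at day 30. Doublets were called in each library with Scrublet as provided in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes up to 10%. Scrublet removed 678 barcodes at day 2, 10 at day 7 and 581 at day 30. It called 1 barcode of 9286 in the untreated library, so the call did not work there. An alternative applied the mean of the day 2 and day 30 thresholds, a score of 0.168, which marked 546 untreated barcodes. The kept cells numbered 6545 untreated, 8310 at day 2, 1920 at day 7 and 6365 at day 30, 23140 of 27230 barcodes in all.

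Kept cells of all libraries were scaled to 10000 UMIs, log-transformed and reduced to 30 principal components of 2000 variable genes. A shared-neighbour graph with 15 neighbours was partitioned by the Leiden method at resolution 1 with seed 0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15). No deposited cell annotation was used. Clusters were called "like" a cell type only from 23 marker lists fixed before the data were examined, as were the 24 gene lists, the size rule below, the rule for named genes and 12 alternatives. A marker led a cluster if its share of cells with a UMI was at least 10% and its level was at least 2-fold that of all other cells. A name needed at least 3 leading markers that made up 25% of the list, and was refused where another class that also met this had more markers among the cluster's top 10 genes. A cluster with no marker of its own class there needed at least 10 leading markers and cells not much shallower than their libraries. Of 39 clusters, 35 were named and 4 were left unnamed, holding 11, 122, 127 and 125 cells in time order. These naming thresholds were set after the clusters had been seen. So were the merging of the injured proximal tubule-like cluster with the other proximal tubule-like clusters, the joining of distal convoluted and connecting tubule clusters, and the grouping of classes into compartments. Without the first of these merges, the smallest number of proximal tubule-like cells would be 48 and the class would not have been among the main ones.

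Within a class, raw UMIs were summed over the cells of a library and divided by the summed total, scaled to 1000000 (CPM). A class was compared between 2 libraries if each held at least 50 of its cells. A gene was measured if it had at least 20 CPM in either library and at least 20 UMIs in both together. By the size rule, a measured gene was called higher or lower if its CPM differed at least 2-fold and the exact 95% interval of the ratio of its Poisson counts excluded 1. For each gene list the members measured, higher and lower were counted. The median of log2((CPM + 10)/(CPM + 10)) was set among the medians of 10000 random lists of the same size and expression level, as a description of these libraries. Shares have exact Clopper-Pearson intervals and CPM values exact Poisson intervals, all at 95%. All intervals cover counting error only, not differences between animals, sorts or captures. A count of 0 was read against a floor of 3 counts. To compare shares of cells with a Clu UMI, each cell was thinned to 2000 UMIs; all kept cells were deeper, so none were left out.

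The named genes follow a fixed rule. The main comparisons are each IRI library against the untreated one in the 3 epithelial classes that passed the marker check with the largest smallest cell number over the 4 libraries. In each, the 5 higher and 5 lower genes with the largest log2 difference were named, among genes that met the size rule with at least 50 CPM and at least 10% of the highest level of any class in that library. Gene models without names, mitochondrially encoded, ribosomal, haemoglobin, immunoglobulin and sex-linked genes were left out of that ranking. Up to 2 higher and 2 lower members of each list with the highest mean CPM were examples, and 9 genes were always followed (Clu, Havcr1, Lcn2, Spp1, Vcam1, Krt8, Krt18, Sox9 and Cdkn1a).

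The calling rule was tested on simulated data, in which counts were redrawn from the mean profile of both libraries at each one's depth. Across the 9 main comparisons, 0 to 0.818% of genes with no simulated difference were called, and 98.0 to 100% of genes with a simulated 4-fold difference were called in the right direction. The simulation holds counting error only, with no difference between cells, animals or captures, so it does not measure false calls between single libraries. The alternatives fixed in advance changed the mitochondrial limit (25%), the UMI minimum (1000), the doublet removal, the Leiden resolution (0.5 and 2), the joint clustering, the scaling (median ratio of measured genes), the weight of cells (mean of each cell's CPM), the pseudocount (1), the filters on level and against the highest class, and the thinning. The 6 added after the data were seen were no mitochondrial limit, a fixed doublet score in the untreated library, CPM without mitochondrial genes, a common UMI minimum of 18362 in every library, subtraction of free RNA, and the proximal tubule-like class without its injured cluster. Free RNA was subtracted as 30% of a gene's mean level over all kept cells of a library, a rough estimate that also removes true signal. It is no upper bound, as Kap stood at 43.7% and Gpx3 at 36.2% of that mean in untreated macrophage-like cells. At day 2 the part varied, from 2.88% for Lyz2 in thick ascending limb-like cells to 54.7% for Kap in thin limb-like cells. A gene below 30% of its library mean is set to 0 by the subtraction. The loss or turn of its call thus does not show that free RNA was its source. Plots were drawn with matplotlib 3.10.9.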

Results

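Clusterin is a secreted chaperone whose transcript, Clu, is known to be induced in injured tubules. The series sampled kidneys of mice with a BAC reporter that ties GFP to Clu, untreated or 2, 7 and 30 days after 35 min of ischemia followed by reperfusion (IRI), and asks whether reporter-positive cells show a maladaptive repair state in the nephron. GFP-positive cells were sorted and read by droplet single-cell RNA sequencing, with 1 library per group. The libraries held 9286 barcodes untreated, 9023 at day 2, 1930 at day 7 and 6991 at day 30, with 68193456, 98818914, 49397016 and 76638427 UMIs. Median depth was 4568.5, 8982, 23394 and 9201 UMIs per barcode, and the lowest was 2335, 3881, 18362 and 5976 UMIs, so the day 7 library lacks all shallow cells. After filtering, 6545, 8310, 1920 and 6365 cells were kept. Mitochondrially encoded genes made up a median of 14.5% of UMIs in kept untreated cells and 2.82, 3.59 and 3.68% at days 2, 7 and 30. All 4 libraries carry a male pattern: Xist had at most 9 UMIs in any of them, while Ddx3y stood at 47.1, 63.6, 51.7 and 72.8 CPM.

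Clu itself is ENSMUSG00000022037 on chromosome 14 (65968483 to 65981547, plus strand of mm10), with 9 annotated transcripts, and the last exon of its principal transcript spans 65981308 to 65981547. Intervals of counts, ratios and shares are exact 95% intervals and cover counting error only. With 1 library per group, no difference was tested, and a difference between libraries may also stem from animals, digestion, sort or capture. CPM stands for UMIs of a gene over all UMIs of the class, scaled to 1000000, and "higher" or "lower" for a difference of at least 2-fold whose counting interval excludes no difference. A gene is said to define clusters if it is among the top 10 genes of a cluster of its class. Other members of the marker lists that named clusters stay in the counts given without defining genes.

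Among sorted GFP-positive cells, kidney epithelium held 88.6% (87.8 to 89.3) of the untreated library, 24.5% (23.6 to 25.5) at day 2, 72.3% (70.2 to 74.3) at day 7 and 54.8% (53.6 to 56.0) at day 30. Blood-derived (haematopoietic) cells were 1.34% (1.08 to 1.65) untreated and 67.5% (66.5 to 68.5), 18.2% (16.5 to 20.0) and 38.0% (36.8 to 39.2) after IRI. At day 2 they were macrophage, monocyte or dendritic-like (37.5% of cells) and neutrophil-like (28.3%; 27.3 to 29.3), the latter an early responder to tissue injury. No neutrophil-like cell was among the 6545 untreated, 1920 day 7 or 6365 day 30 cells, with upper limits of 0.0563%, 0.192% and 0.0579%. The day 2 ones had a median of 5025 UMIs, below the lowest totals of the day 7 and day 30 libraries, so such cells may have been lost there. Proximal tubule-like cells, which reclaim most of the filtrate and are the main site of ischemic damage, were 43.5% (42.3 to 44.7) of untreated cells and 1.42% (1.18 to 1.70), 37.1% (34.9 to 39.3) and 12.9% (12.1 to 13.7) of the later ones. Thick ascending limb-like cells held 10.3, 7.30, 6.98 and 9.82%. Thin limb-like cells, whose name is less sure after IRI, held 1.36, 1.02, 19.8 and 10.4%. Endothelial-like cells held 8.31, 4.16, 0.104 and 2.07%, and fibroblast-like cells 0.0153, 1.95, 2.81 and 2.89%.

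These shares depend on the sort and on the UMI floors of 2335, 3881, 18362 and 5976. Above the day 7 floor of 18362 UMIs in every library, 601, 988, 1920 and 495 cells remained. Haematopoietic cells were then 0.166, 49.3, 18.2 and 30.9% of them, epithelium 97.5, 44.9, 72.3 and 66.9%, proximal tubule-like cells 60.7, 2.23, 37.1 and 28.1%, thick ascending limb-like cells 10.3, 14.7, 6.98 and 8.89%, thin limb-like cells 3.16, 0.911, 19.8 and 12.9%, endothelial-like cells 2.33, 0.405, 0.104 and 0.404%, and fibroblast-like cells 0, 1.72, 2.81 and 0.606%. The day 2 thick ascending limb-like share thus lies below the untreated one over all cells and above it at the common floor. Parietal epithelial-like cells were 13.5% (12.6 to 14.3) of day 30 cells (7.27% above the floor) against 0.550, 0.927 and 0.365% before. All lie in cluster 8, where 857 cells come from day 30, so the cluster may reflect that library rather than a cell type. Its top 10 genes hold 1 marker of its own class, Ncam1, and are led by Tagln, on the pericyte, mesangial or smooth muscle list. The day 30 epithelial shares of 54.8% and, above the floor, 66.9% include these cells and carry that doubt. A macrophage-like cluster of 1805 cells has 21 leading markers of its class. Its top 10 genes, however, hold Pf4, a marker on the platelet list, and no marker of its own class. The class thus failed the marker check: no gene list was compared in it, and its share and Clu level carry that doubt. Unnamed clusters held 0.168, 1.47, 6.61 and 1.96% of cells and were led by genes such as Ccl8, Ccr7, Cenpf and Mt2.

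**Figure D1:**
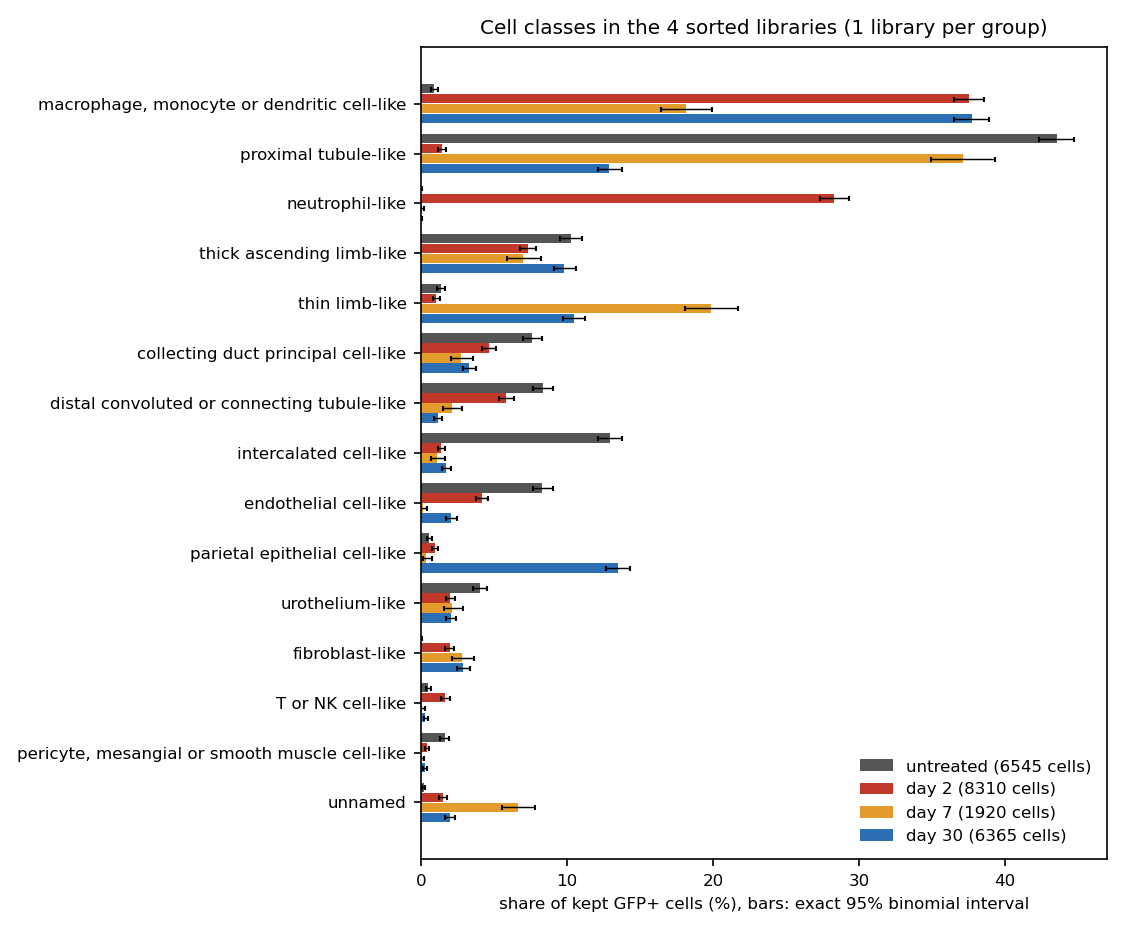
Share of kept GFP-positive cells in each marker-named class of the 4 libraries. Lines show exact 95% binomial intervals, which cover counting error only.

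Clu, the gene behind the sort, stood at 234 CPM (229.6 to 238) over all untreated cells, 2468 (2458 to 2479) at day 2, 1373 (1363 to 1383) at day 7 and 660.4 (654 to 667) at day 30. That is 10.6-fold (10.4 to 10.8), 5.88-fold (5.76 to 5.99) and 2.83-fold (2.77 to 2.88) the untreated level. Among cells above the common UMI floor, the same ratios were 37.3, 13.8 and 6.63. After each cell was thinned to 2000 UMIs, 16.8% (15.9 to 17.7), 43.6% (42.6 to 44.7), 54.5% (52.2 to 56.7) and 38.2% (37.0 to 39.4) of cells had a Clu UMI. The lowest backgrounds were 3.81% of untreated pericyte-like cells (median depth 4561 UMIs), 22.3% of day 2, 19.8% of day 7 and 14.8% of day 30 macrophage-like cells (median depths 11618, 22236.5 and 8682). Neutrophil-like cells at day 2 had a Clu UMI in 36.8% (34.8 to 38.8) of cells. A class share at or below these values is read as background. Macrophage-like cells made up 37.5% of the sorted day 2 cells, yet their Clu stood at 122 CPM (118 to 125), 4.93% of the library mean. Why the sort took cells with so little Clu was not tested.

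By class, principal cell-like cells of the collecting duct had the highest Clu after IRI: 15462 CPM at day 2, 14505 at day 7 and 5647 at day 30 against 828 untreated. These are 18.7-fold (18.1 to 19.3), 17.5-fold (17.0 to 18.1) and 6.82-fold (6.60 to 7.06). Thick ascending limb-like cells had the largest ratio at day 2, 59.3-fold (54.5 to 64.7), with 5822, 2522 and 1561 CPM against 98.2. A Clu UMI was found in 10.1% of thinned untreated cells of that class and in 90.4, 82.1 and 70.9% later, and in 45.7, 99.5, 98.1 and 86.7% of principal cells. Thin limb-like cells had 477, 1244 and 508 CPM against 83.0 (5.74-fold, 4.62 to 7.19; 15.0-fold, 12.3 to 18.4; 6.13-fold, 5.03 to 7.54). The day 2 level is 19.3% of the library mean. That is below the 30% subtracted as free RNA, so the subtraction turns it to the lower side by construction. Free RNA is not excluded as its source. Proximal tubule-like cells had only 307 (281 to 335), 508 and 514 CPM against 22.7 (13.6-fold, 12.0 to 15.3; 22.4-fold, 20.5 to 24.5; 22.7-fold, 20.8 to 24.8). Their untreated level stood beside 32.3 CPM in pericyte-like cells (ratio 0.701, 0.434 to 1.21), and the thinned share with a Clu UMI was 6.84% against 3.81%, so background is not excluded. Their day 2 share with a Clu UMI, 39.8% (30.9 to 49.3), stood beside 36.8% in neutrophil-like cells, and their 307 CPM beside 232 (223 to 239.8). Distal convoluted or connecting tubule-like cells had 8383 and 2503 CPM at days 2 and 30 against 1044, intercalated-like cells 1979 and 979 against 198, and urothelium-like cells 2252 and 710.03 against 305. Endothelial-like cells, at 413 and 377 against 282 CPM, stayed within 2-fold. From day 2 to day 30 the level in the thick ascending limb-like class was 0.268-fold (0.262 to 0.274) and in principal cells 0.365-fold, whereas in proximal tubule-like cells it was 1.67-fold (1.53 to 1.83). Clu itself helps define the principal cell and distal tubule clusters, so its level in those classes is partly set by the clustering. Intercalated-like cells lie in cluster 9 untreated (98.5%) and in cluster 28 at days 2 and 30 (100 and 98.2%). Distal convoluted or connecting tubule-like cells lie in cluster 20 untreated (99.8%) and in cluster 21 at days 2 and 30 (99.8 and 52.8%). Differences in Clu in these classes may thus in part be between cell types. The same holds for thick ascending limb-like cells, in clusters 12 untreated (98.2%), 15 at day 2 (91.8%) and 11 at day 30 (92.5%). Principal cells lay in cluster 22 untreated (98.4%) and in cluster 19 at days 2 and 30 (98.7 and 67.1%). The injured cluster 3 held 32.2% of proximal tubule-like cells at day 2 and 74.9% at day 30, so their 1.67-fold may in part follow that make-up.

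**Figure D2:**
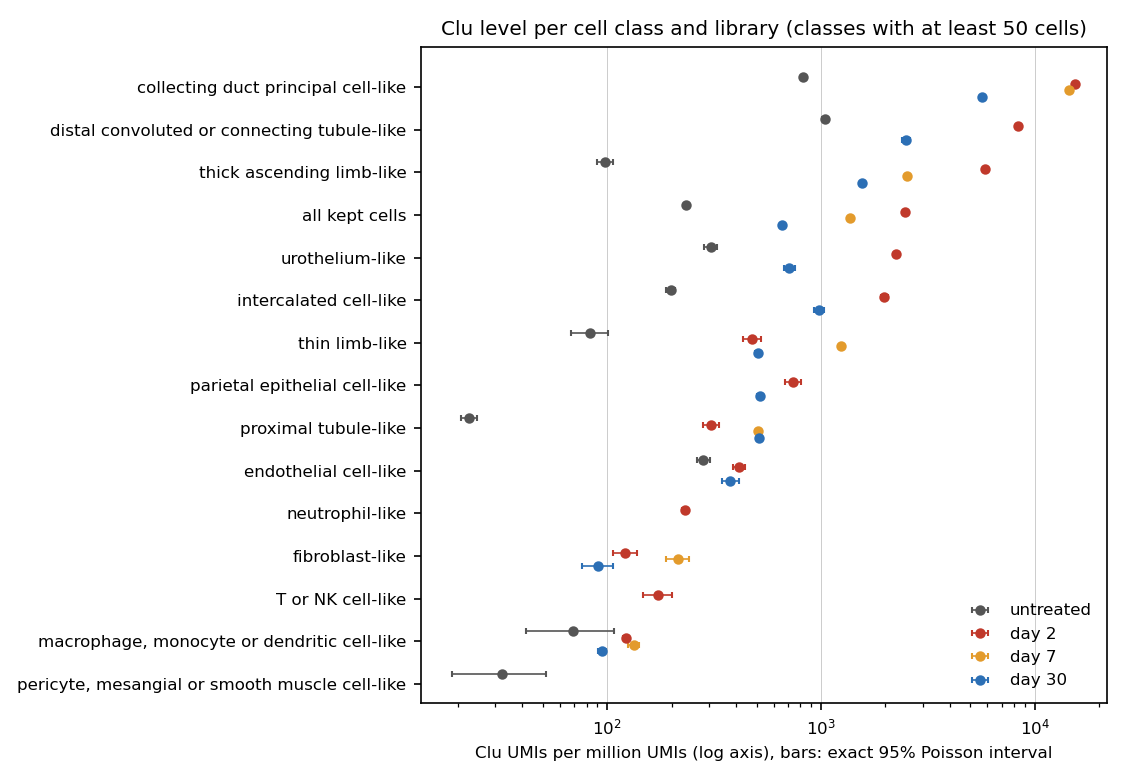
Clu in CPM in each marker-named class and library, on a log axis. Lines show exact 95% Poisson intervals, which cover counting error only.

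At day 2, proximal tubule-like cells carried genes of tubular injury at far higher levels than untreated ones. Spp1 (osteopontin) stood at 9898 against 385 CPM, 25.7-fold (25.04 to 26.4), the actin-binding Tmsb10 at 390.4 against 10.7 CPM, 36.4-fold (31.4 to 42.2), and Anxa2, a membrane-binding annexin, at 270.3 against 8.40 CPM, 32.2-fold (27.2 to 38.2). Krt18, a keratin of simple epithelia, was higher 22.2-fold (18.9 to 26.1), its partner Krt8 6.31-fold (5.81 to 6.85), and Sox9, a transcription factor of tubule repair, 27.0-fold (19.2 to 38.4). Of the injury list, 19 of 23 measured genes were higher without Havcr1, the kidney injury marker that helps define the injured cluster (median log2 difference of the full list 2.59, percentile 100 of random lists); S100a6 stood at 1712 against 21.8 CPM. Of the failed-repair list, 12 of 12 were higher without Vcam1 and Cxcl1, among them Adamts1 (191 against 24.6 CPM). At all times both lists keep other genes of the marker list that named the injured cluster. Examples are Krt20, Tnfrsf12a and Gdf15 in the injury list and Dcdc2a, Sema5a, Ccl2, Akap12 and Kcnip4 in the failed-repair list. Their counts are thus not free of genes that chose the cluster. The defining genes Havcr1 and Vcam1 stood at 182 against 2.79 CPM and 217 against 5.91 CPM.

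Repair and developmental regulators were higher in 10 of 14 genes at day 2 (Klf6, 288 against 24.9 CPM; Egr1, 115 against 28.6 CPM), and cell cycle genes in 11 of 14 (Hmgb2, 206 against 50.7 CPM; Stmn1, 197 against 56.9 CPM). Adhesion genes were higher in 15 of 18 (Itgb1, 259 against 88.5 CPM), interferon response genes in 6 of 6 (B2m, 503 against 94.2 CPM), complement and acute phase genes in 6 of 7 (C3, 285 against 11.9 CPM), matrix genes in 8 of 11 (Sparc, 297 against 21.7 CPM), and MHC class II genes in 6 of 6 (Cd74, 201 against 16.2 CPM). Senescence genes were higher in 5 of 10, or 3 with 1 lower under median scaling; the arrest gene Cdkn1a stood at 47.2 against 8.53 CPM, 5.54-fold (4.21 to 7.22). The dissociation immediate-early list, a sign of handling, was higher in 14 of 14 genes (Jun, 671 against 80.4 CPM). It shares Atf3 and Egr1 with the repair list and Btg2 with the senescence list, so handling may enter those counts in every class. Injury shares members with the adhesion list (such as Krt8 and Krt18) and with the complement list (Lcn2 and Cp).

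Lower at day 2 were 7 of 19 proximal tubule transport and metabolism genes that do not define clusters, with 2 higher, among them the amino acid carrier Slc7a7 (227 against 97.8 CPM). Fatty acid oxidation, the main fuel route of this segment, had 7 lower and 3 higher of 23, or 12 and 1 under median scaling; Acadm was lower (265 against 800.0 CPM). Oxidative phosphorylation genes were lower in 2 of 20, or 14 under median scaling. The lower genes by rank were Kap, Slc7a13, Slco1a1, Inmt and Acsm3, all of which define clusters (Kap, 1811 against 50952 CPM). The day 2 class has 118 cells, 57.6% of them in cluster 18 and 32.2% in the injured cluster 3, against 2849 untreated cells in clusters 6, 10, 13 and 18.

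Over all measured genes the median log2 difference of proximal tubule-like cells was 0.36, 0.54 and 0.50 at days 2, 7 and 30, so counts of higher genes are partly a shift of all genes. Of all measured genes in the class, 19.7, 35.3 and 33.4% were higher and 4.56, 9.47 and 7.62% lower. In every class, a gene near 0 in untreated cells is measured only if it is high after IRI. Counts in which all measured members are higher are thus partly set by this filter. Under median scaling their log2 differences shift by -0.51 at day 2, -0.67 at day 7 and -0.68 at day 30, and mitochondrially encoded genes took 22.4% of the class's UMIs untreated and 13.1, 5.33 and 7.29% later. Subtraction of free RNA ends the day 2 calls of Clu, Lcn2 (70.0 against 1.06 CPM) and Cdkn1a and leaves no MHC class II gene measured. Genes of haematopoietic cells stood higher at day 2 as well, S100a8 at 646 against 3.97 CPM and Tyrobp at 183 against 1.10. Lyz2 had 194, 419 and 504 CPM at days 2, 7 and 30 against 0.422. Part of the immune lists of this class may thus be free RNA. So may part of its matrix list, as fibroblast-like cells numbered 1 untreated and 184 at day 30. Col1a1, a fibroblast marker, stood at 24.6 CPM in proximal tubule-like cells at day 30, beside 32.2 in macrophage-like cells. At day 2 the subtraction leaves higher, of the full lists, 9 adhesion, 5 cell cycle, 3 complement and acute phase, 8 failed-repair, 3 immediate-early, 1 interferon response and 3 senescence genes, with fatty acid oxidation at 4 higher and 4 lower and oxidative phosphorylation at 0 lower. In every class the filter on level applies after the subtraction and leaves out genes it brings below the minimum. A smaller count is thus not in itself a lost difference. Removal of the injured cluster ends the calls of Havcr1, Krt8, Sox9 and Cdkn1a and leaves higher 13 injury, 8 adhesion, 3 cell cycle, 5 failed-repair, 3 interferon response and 5 repair genes, with transport and metabolism at 8 higher and 8 lower.

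At day 7 the proximal tubule-like class had its highest Spp1, S100a6 and Lcn2, with 93.3% of its 712 cells in the injured cluster. Spp1 stood at 42565 against 385 CPM, 110.5-fold (108 to 113), the calcium-binding S100a6 at 2931 against 21.8 CPM, 134-fold (123 to 147), Tmsb10 at 1415 against 10.7 CPM, 132-fold (117 to 149.9), and Lcn2, an iron-chelating marker of tubular damage, at 245 against 1.06 CPM, 232-fold (157 to 358). Of injury genes 23 of 26 were higher without Havcr1, and 1 was lower, the protease inhibitor Timp3 (533 against 1492 CPM). Of failed-repair genes 19 of 20 were higher without Vcam1 and Cxcl1 (Adamts1, 513 against 24.6 CPM). Krt18 was higher 21.0-fold (18.5 to 24.0), Krt8 6.27-fold (5.96 to 6.59), Sox9 45.2-fold (34.4 to 60.6) and Cdkn1a 10.99-fold (9.50 to 12.8).

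Matrix genes were higher in 19 of 19 at day 7 (the basement membrane collagen Col4a1, 497 against 53.0 CPM; the integrin Itgb6, 297 against 80.5 CPM), interferon response genes in 14 of 14 (Psmb8, 129 against 3.04 CPM), and MHC class II genes in 6 of 6 (the invariant chain Cd74, 1277 against 16.2 CPM). Complement and acute phase genes were higher in 8 of 9 (C3, 535 against 11.9 CPM), adhesion genes in 17 of 20 (Itgb1, 521 against 88.5 CPM), and repair regulators in 14 of 16 (Klf6, 657 against 24.9 CPM), or 12 with 2 lower under median scaling. Senescence genes were higher in 6 of 10 with 1 lower, or 4 with 2 lower under median scaling; the median of the list stood at percentile 93.7 of random lists. Immediate-early genes were higher in 14 of 14 (Jun, 868 against 80.4 CPM). Heat shock genes were higher in 5 of 11, with Hspb1 at 983 against 7.94 CPM, or 3 with 2 lower under median scaling, and at percentile 70.4 the list does not stand out.

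Transport genes were low at day 7: 15 of 19 transport and metabolism genes that do not define clusters were lower and 0 higher. Of genes by rank, Ttr, the thyroid hormone carrier, stood at 4.95 against 878 CPM, beside Kap, Inmt, Slc7a13 and Dnase1, all of which define clusters. Fatty acid oxidation genes were lower in 12 of 20 (Acadm, 270.0 against 800.0 CPM) and oxidative phosphorylation genes in 8 of 20 (Cycs, 508 against 1297 CPM), or 17 under median scaling. At day 7 median scaling leaves 9 interferon response genes higher. Among the genes still measured, subtraction of free RNA leaves higher 8 interferon response, 12 matrix and 3 heat shock genes, and 4 oxidative phosphorylation genes lower. Without the injured cluster 48 cells remained, too few to compare.

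At day 30 injury and failed-repair genes were still high in proximal tubule-like cells, 74.9% of whose 821 cells lay in the injured cluster. Tmsb10 stood at 1115 against 10.7 CPM, 104-fold (91.8 to 118), S100a6 at 1716 against 21.8 CPM, 78.6-fold (72.0 to 86.0), Crip1, a small LIM-domain protein, at 1062 against 16.6 CPM, 63.8-fold (57.7 to 70.7), and Spp1 at 13402 against 385 CPM, 34.8-fold (34.1 to 35.5). Sox9 was higher 96.9-fold (73.9 to 129.8), more than at earlier times, and Lcn2 185-fold (125 to 287). Krt8 (10.5-fold), Krt18 (30.0-fold) and Cdkn1a (10.6-fold) were also higher. The defining Vcam1, an adhesion molecule of failed-repair tubules, kept 1129.5 CPM beside 1295 at day 7, while Havcr1 stood at 81.9 beside 892.

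Failed-repair genes were higher in 20 of 20 at day 30 without Vcam1 and Cxcl1 (Adamts1, 431 against 24.6 CPM), injury genes in 25 of 27 without Havcr1, and matrix genes in 24 of 24 (Col4a1, 464 against 53.0 CPM; Sparc, 423 against 21.7 CPM). Adhesion genes were higher in 18 of 20 (Epcam, 539 against 20.3 CPM), interferon response genes in 10 of 10, or 5 of 6 under median scaling (B2m, 666 against 94.2 CPM), and MHC class II genes in 6 of 6 (H2-Aa, 456 against 5.40 CPM). Complement and acute phase genes were higher in 7 of 8 (the copper carrier Cp, 445 against 7.31 CPM), and senescence genes in 10 of 13 with 2 lower, or 6 and 2 under median scaling (Btg2, 244 against 15.5 CPM). Immediate-early genes were higher in 14 of 14 (Egr1, 336 against 28.6 CPM). Cell cycle genes were higher in 5 of 8, or 1 with 1 lower under median scaling, beside 11 at day 2.

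Transport and metabolism genes that do not define clusters were lower in 14 of 19 at day 30 and higher in 0, such as the anion transporter Slc22a8 (10.0 against 236 CPM). The defining Ttr and Miox stood at 36.9 against 878 CPM and 147 against 2755 CPM. Oxidative phosphorylation genes were lower in 11 of 20 (Cox4i1, 1009 against 2316 CPM), or 19 under median scaling, and fatty acid oxidation genes in 9 of 22 with 1 higher, or 17 and 1 under median scaling (Acaa1b, 72.3 against 321 CPM). Of the full lists, defining genes included, 20 of the 26 injury genes higher at day 30 were already higher at day 2, as were 14 of 22 failed-repair and 8 of 24 matrix genes, while 13 of 26 transport genes were lower at both times. Only 14 failed-repair and 11 matrix genes were measured at day 2, so a low overlap there does not mark a late onset. Without the injured cluster the calls of Lcn2, Krt8, Krt18 and Sox9 end, and the full lists have higher 14 injury, 9 failed-repair, 9 adhesion, 4 interferon response, 11 matrix, 3 senescence and 0 cell cycle genes. Lower are then 6 transport and 4 oxidative phosphorylation genes, and fatty acid oxidation turns to 4 higher and 2 lower. Clustering each library alone left 17 injury genes higher and 6 transport genes lower and ends the calls of Lcn2, Krt8 and Krt18. Subtraction of free RNA ends the call of Cd74 (1439.6 against 16.2 CPM) and leaves no MHC class II gene measured. Among the genes still measured it leaves higher 4 interferon response, 14 matrix, 6 senescence and 2 cell cycle genes, and 6 oxidative phosphorylation genes lower.

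**Figure D3:**
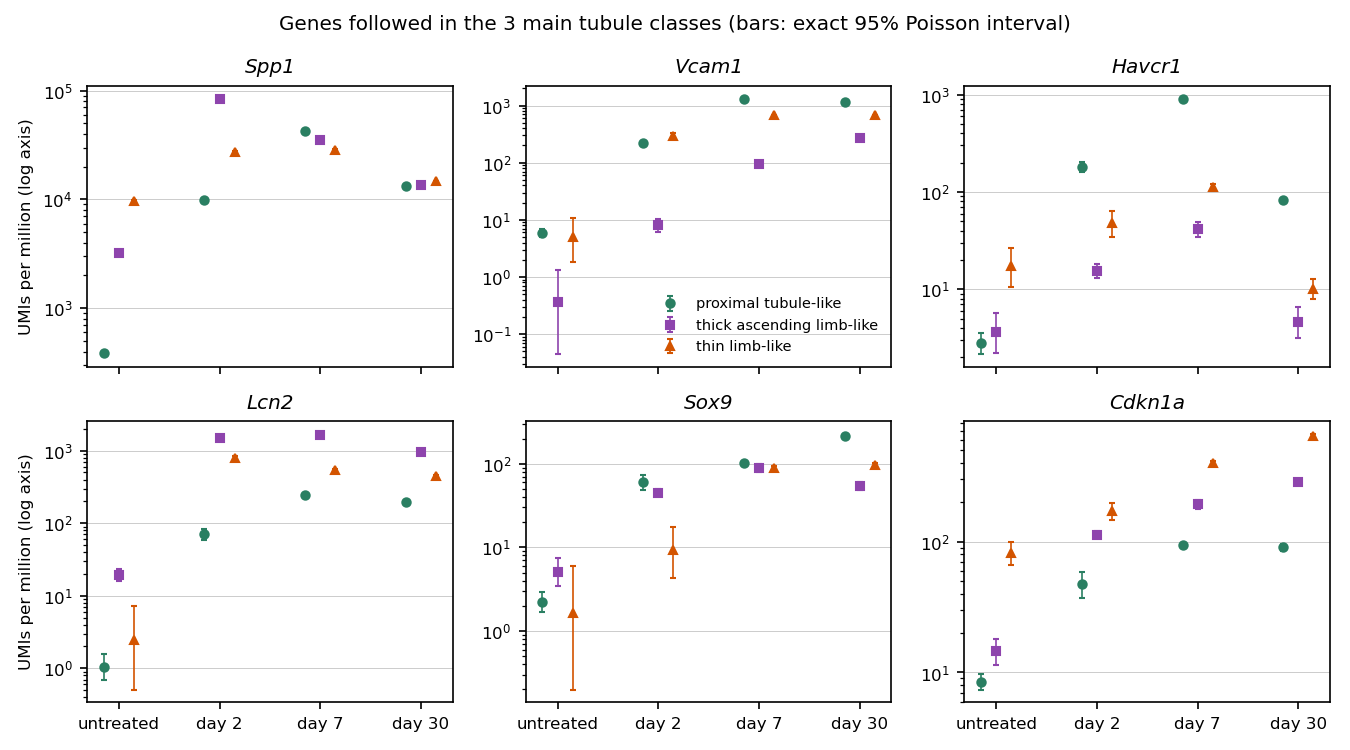
Levels of 6 genes of injury, failed repair and arrest in the 3 main epithelial classes of the 4 libraries, on a log axis. Lines show exact 95% Poisson intervals, which cover counting error only.

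In thick ascending limb-like cells, which dilute the urine and make uromodulin, day 2 showed higher injury genes and lower salt transport and respiration genes. Lcn2 stood at 1497 against 19.2 CPM, 77.9-fold (64.3 to 95.3), the matrix protease Adamts1 at 366 against 6.78 CPM, 54.0-fold (39.1 to 76.9), Tmsb10 at 954 against 49.8 CPM, 19.1-fold (17.0 to 21.7), and Clu at 5822 against 98.2 CPM. Injury genes other than the defining Spp1 were higher in 16 of 23 (S100a11, 2023 against 245 CPM), failed-repair genes in 8 of 11 without Prom1 (Dcdc2a, 245 against 16.8 CPM), and repair regulators in 10 of 14 (Cd24a, 1733 against 384 CPM; Klf6, 626 against 92.3 CPM). Adhesion genes were higher in 13 of 16 (Cd9, 1102 against 277 CPM; Cldn7, 517 against 135 CPM). Krt8 was higher 4.63-fold, Krt18 3.65-fold, Sox9 8.79-fold and Cdkn1a 7.81-fold.

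Genes of oxidative phosphorylation, by which mitochondria make ATP, were lower in 19 of 20 at day 2 (Cox4i1, 1056 against 3607 CPM; Cox6c, 1329.6 against 2921 CPM) and fatty acid oxidation genes in 8 of 17 with 1 higher; their regulator Ppargc1a stood at 68.0 against 296 CPM. Of transport genes that do not define clusters, 6 of 11 were lower; the defining Umod and Slc12a1, the target of furosemide, stood at 6502 against 15094 CPM and 1705 against 5579 CPM. Heat shock genes were higher in 3 of 11 (Hspb1, 434 against 24.9 CPM), or 3 with 2 lower under median scaling, and the list does not stand out (percentile 33.1). Matrix genes were higher in 9 of 13 (Itgav, 286 against 113 CPM), interferon response genes in 5 of 6 (B2m, 103 against 37.0 CPM), senescence genes in 4 of 8 with 1 lower, or 2 lower under median scaling (Gadd45a, 145 against 30.4 CPM), and immediate-early genes in 13 of 14 (Jun, 754 against 265 CPM). The glycolytic Hk2 was higher (41.5 against 1.10 CPM) in a hypoxia and glycolysis list with 1 higher and 4 lower of 16.

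Among the lower genes by rank at day 2, Kap, Acsm2, Gpx3 and Slc34a1 belong to the proximal tubule. Kap stood at 7769 CPM in untreated thick ascending limb-like cells, below the 14747 CPM of pericyte-like cells in that library, so these are read as free RNA; the lower proximal tubule genes in this class and in the thin limb are not results. Thick ascending limb-like log2 differences shift by -0.13, -0.46 and -0.45 at days 2, 7 and 30 under median scaling (the median of all measured genes is 0.13, 0.39 and 0.40), and mitochondrial genes took 22.4% of the class's UMIs untreated and 7.64, 4.22 and 6.90% later. The class lies in cluster 12 untreated (98.2%), 15 at day 2 (91.8%), 11 and 15 at day 7 (59.0 and 41.0%) and 11 at day 30 (92.5%), so its libraries hardly mix. Lyz2, a gene of myeloid cells, stood at 95.7, 206 and 494 CPM against 0.366 in this class. Part of its immune lists may thus be free RNA. Col1a1 stood at 33.0 CPM in this class at day 30, beside 32.2 in macrophage-like cells. Free RNA of fibroblasts may thus enter its matrix list. At day 2 interferon response genes are 3 higher and 1 lower under median scaling, and none is measured after subtraction of free RNA, which leaves 3 failed-repair and 2 senescence genes higher and 4 fatty acid oxidation genes lower.

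At day 7 the same class carried Lcn2 at 1643 against 19.2 CPM, 85.5-fold (70.4 to 105), S100a6 at 7099.8 against 127 CPM, 56.1-fold (52.0 to 60.6) and Adamts1 at 467 against 6.78 CPM, 68.9-fold (49.8 to 98.3), with Krt18 higher 16.9-fold, Krt8 9.98-fold, Sox9 17.4-fold and Cdkn1a 13.3-fold. Injury genes without Spp1 were higher in 23 of 27, failed-repair genes without Prom1 in 13 of 17 (Dcdc2a, 276 against 16.8 CPM), and matrix genes without Mmp7 in 17 of 21 (Col18a1, 234 against 54.2 CPM; Itgav, 337 against 113 CPM). Senescence genes were higher in 11 of 15, or 7 with 2 lower under median scaling, repair regulators in 12 of 16, adhesion genes in 15 of 18 (Cd9, 872 against 277 CPM) and immediate-early genes in 12 of 14 (Jun, 861 against 265 CPM). Oxidative phosphorylation genes were lower in 19 of 20 (Cox4i1, 1127 against 3607 CPM), fatty acid oxidation genes in 8 of 15 (Ppargc1a, 83.2 against 296 CPM), or 13 under median scaling and 4 after subtraction of free RNA, and non-defining transport genes in 8 of 11. Vcam1 stood at 93.3 CPM against 2 untreated UMIs, 255-fold (69.9 to 2114); subtraction of free RNA ends its call, leaves 8 failed-repair and 10 matrix genes of the full lists higher, and turns Havcr1 (41.3 against 3.66 CPM) to the lower side.

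At day 30 thick ascending limb-like cells kept Lcn2 at 969 against 19.2 CPM, 50.4-fold (41.6 to 61.7), Adamts1 at 508 against 6.78 CPM, 74.9-fold (54.3 to 107), S100a6 at 3585 against 127 CPM, 28.3-fold (26.3 to 30.6) and Anxa1, a mediator of resolving inflammation, at 370.0 against 4.76 CPM, 77.7-fold (52.9 to 119). Vcam1 stood at 266 CPM against 2 untreated UMIs, 725-fold (200.4 to 5992), and Cdkn1a was higher 19.8-fold (15.8 to 25.1), beside 10.5-fold for Sox9 and 6.98-fold for Krt18. Havcr1 was not measured, with 4.66 against 3.66 CPM, a difference whose direction turned under 4 other settings. Injury genes without Spp1 were higher in 21 of 24, failed-repair genes without Prom1 in 18 of 20 (Tnfaip2, 328 against 111 CPM), repair regulators in 14 of 17 (Klf6, 1129.8 against 92.3 CPM), and interferon response genes in 10 of 11 with 1 lower, or 5 and 1 under median scaling and 4 and 0 after subtraction of free RNA (Ifitm3, 117 against 24.0 CPM; B2m, 306 against 37.0 CPM). MHC class II genes were higher in 5 of 5 (H2-Aa, 339 against 3.30 CPM), none of them measured after subtraction of free RNA. Immediate-early genes were higher in 13 of 14 (Fos, 1975 against 138 CPM), and senescence genes in 8 of 12 with 2 lower, or 4 and 2 under median scaling and 5 and 0 after that subtraction.

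Transcripts of respiration genes stayed low at day 30: oxidative phosphorylation genes were lower in 19 of 20 (Cox4i1, 966 against 3607 CPM), 19 of which were lower at day 2 already, and fatty acid oxidation genes in 10 of 15 (Hadhb, 87.1 against 229 CPM), or 3 after subtraction of free RNA. Other classes had lower genes of these lists too. At days 2 and 30, 10 and 8 fatty acid oxidation genes were lower in endothelial-like cells. Oxidative phosphorylation genes lower were 10 and 5 there, 13 and 6 in intercalated-like and 17 and 0 in distal convoluted or connecting tubule-like cells. Kap stood at 29.2% of its library mean in untreated thick ascending limb-like cells, so less proximal tubule free RNA may enter the fatty acid oxidation counts. Non-defining transport genes were lower in 10 of 11 (the sodium pump modulator Fxyd2, 2745 against 7347 CPM). Of genes lower by rank, Nccrp1 defines a cluster and Kap, Miox, Dnase1 and Acsm2 are read as free RNA. Of the full lists, defining genes included, 17 injury and 8 failed-repair genes were higher and 12 transport genes lower at all 3 times.

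**Figure D4:**
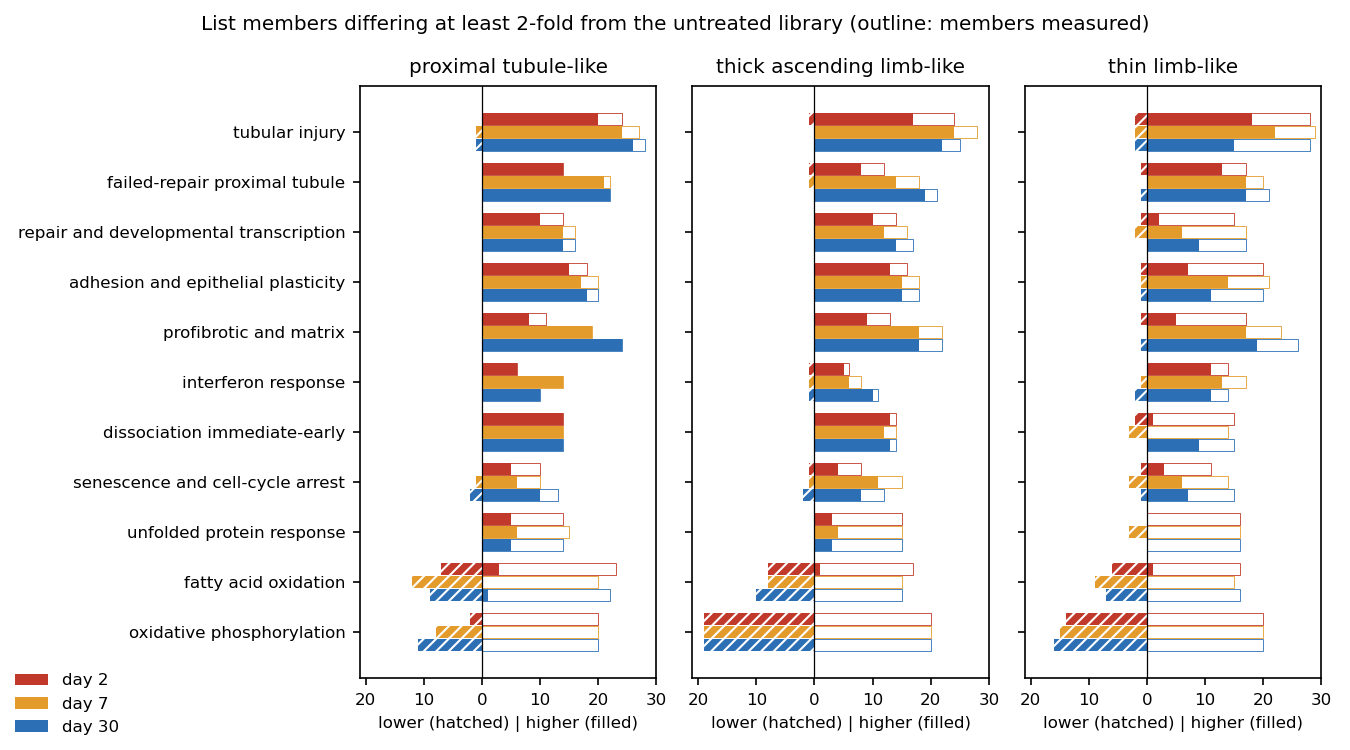
Members of 11 gene lists measured (outline), higher (filled) and lower (hatched) than untreated in the 3 main classes at each time. Counts include genes that help define clusters and carry no test.

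In thin limb-like cells, which line the loop of Henle in the medulla, day 2 showed higher injury, failed-repair and interferon genes. Lcn2 stood at 785 CPM against 3 untreated UMIs, 318-fold (108 to 1547); the metal-binding Mt2 at 388 against 8.22 CPM, 47.2-fold (25.4 to 99.2); Vcam1 at 288 against 4.93 CPM, 58.5-fold (26.5 to 161); and Cd14, a receptor for bacterial lipopolysaccharide, at 505 against 18.1 CPM, 28.0-fold (18.3 to 45.0). Injury genes without Cryab were higher in 18 of 27 and lower in 1 (S100a6, 5223 against 1586 CPM; Timp3, 209.8 against 2302 CPM). Failed-repair genes were higher in 13 of 17 (Adamts1, 592 against 36.2 CPM; the neutrophil-attracting Cxcl2, 735 CPM against 1 untreated UMI, 894-fold (160.0 to 35373)), interferon response genes without Ifit3 in 11 of 13 (B2m, 436 against 97.0 CPM), and complement and acute phase genes in 6 of 7 with 1 lower. Oxidative phosphorylation genes were lower in 14 of 20 (Cox4i1, 1009.9 against 2607 CPM), and hypoxia and glycolysis genes in 6 of 16 with 1 higher (Eno1, 235 against 676 CPM; Hk2, 92.0 against 10.7 CPM).

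Lower by rank at day 2 were Car14, a carbonic anhydrase, with 0 UMIs and thus at least 88.5-fold lower, and the defining Npy, Lypd2 and Aqp1, the water channel. NRF2 genes were higher in 4 and lower in 3 of 17 (Mt1, 1248 against 129.8 CPM; Gclm, 658 against 183 CPM; percentile 56.4 for the list). Spp1 was higher 2.84-fold (2.78 to 2.91), Krt8 3.55-fold and Krt18 3.11-fold. The class lies in cluster 35 untreated (87.6%) and almost wholly in cluster 5 later, with 89, 85, 381 and 665 cells, and the name of cluster 5 rests on 8 leading markers, with Aqp1 low there. Injured cells of another segment are not excluded in cluster 5, so the differences in this class may in part be between cell types. Umod, a thick ascending limb gene, stood at 573, 105 and 263 CPM in the class at days 2, 7 and 30. In macrophage-like cells it stood at 46.4, 56.8 and 63.5 CPM. RNA or cells of the thick ascending limb may thus carry part of the differences, such as that of Lcn2. Genes of haematopoietic cells were high in the class at day 2, S100a8 at 870.3 against 0.822 CPM, Tyrobp at 168 against 0 and Lyz2 at 106 against 0, and Lyz2 reached 243 and 497 CPM later. Free RNA may thus carry part of the Cxcl2, interferon and complement differences, while Cd14 was at 78.3% of its library mean beside 11.5% for S100a8. Subtraction of free RNA leaves 9 of 14 failed-repair and 4 complement and acute phase genes higher, turns Clu to the lower side at day 2, leaves 4 interferon response genes higher and ends the call of Cdkn1a (171 against 82.2 CPM), which also ends with doublets kept, with a 25% mitochondrial limit and with the mean CPM of cells.

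At day 7 thin limb-like cells carried Vcam1 at 676 against 4.93 CPM, 137-fold (63.0 to 374), the protease Adamts5 at 391 against 7.40 CPM, 52.9-fold (27.8 to 116), Basp1 at 384 CPM against 0 untreated UMIs (at least 156-fold), and Cxcl2 at 365 CPM against 1 UMI, 445-fold (79.7 to 17567). Injury genes without Cryab were higher in 22 of 28 (S100a6, 7050.4 against 1586 CPM), failed-repair genes in 17 of 20 (Adamts1, 851 against 36.2 CPM), matrix genes in 17 of 23 (Col4a1, 1003 against 159 CPM; Col4a2, 444 against 91.2 CPM), adhesion genes in 14 of 21, and interferon response genes without Ifit3 in 13 of 16 (Psmb8, 129 against 13.1 CPM). Of senescence genes 6 were higher and 3 lower of 14 (Btg2, 349 against 1078 CPM), and Cdkn1a was higher 4.88-fold (4.00 to 6.01). Lcn2 stood at 544 CPM, and Krt18 and Krt8 were higher 5.53-fold and 5.51-fold. Immediate-early genes were lower in 3 and higher in 0 of 14 (Ier2, 420.1 against 1055 CPM). Lower were oxidative phosphorylation genes in 15 of 20 (Ndufa4, 864 against 1912 CPM) and NRF2 genes in 5 with 3 higher of 16 (Gstm1, a glutathione transferase, 92.7 against 1092 CPM; percentile 13.4 for the list). Lower by rank were the defining Npy, Fmo2, Aqp1 and Lypd2, and Car14 with 1 UMI, 2625-fold (468 to 104005) lower. Subtraction of free RNA turns Havcr1 (113 against 17.3 CPM) to the lower side and leaves 6 immediate-early genes lower.

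At day 30 thin limb-like cells kept Vcam1 at 673 against 4.93 CPM, 137-fold (62.7 to 372) and Cdkn1a at 645 against 82.2 CPM, 7.85-fold (6.44 to 9.66), its highest level in the class. Lcn2 stood at 441 CPM against 3 untreated UMIs, 179-fold (61.2 to 868), Plac8 at 265 against 3 UMIs, 107-fold (36.7 to 522), and Cxcl2 and Anxa1 at 263 and 260.3 against 1 UMI each, 320.1-fold (57.4 to 12650.1) and 317-fold (56.8 to 12518). Failed-repair genes were higher in 17 of 21 (Adamts1, 831 against 36.2 CPM), matrix genes in 19 of 26, injury genes without Cryab in 15 of 27 (Tmsb10, 971 against 131 CPM), repair regulators in 9 of 17 (Atf3, 2398 against 470.1 CPM), and immediate-early genes in 9 of 15 (Fos, 4849 against 2216 CPM). Senescence genes were higher in 7 of 15, interferon response genes without Ifit3 in 11 of 13 (Irf1, 139.8 against 33.7 CPM), and complement and acute phase genes in 5 of 7 (Cp, 517 against 42.7 CPM). Hypoxia and glycolysis genes were lower in 10 of 16 (Gapdh, 631 against 1263 CPM; Aldoa, 324 against 930.3 CPM), oxidative phosphorylation genes in 16 of 20 (Cox4i1, 769.9 against 2607 CPM) and cholesterol synthesis genes in 5 of 11 (Fdps, 20.0 against 51.8 CPM). Besides the defining genes, Fxyd2 was lower, 137 against 4443 CPM, 32.5-fold (30.4 to 34.8). Spp1 stayed within 2-fold (14666 against 9615 CPM) and Havcr1 was not measured. Of the full lists, defining genes included, 13 injury and 12 failed-repair genes were higher and 14 oxidative phosphorylation genes lower at all 3 times. Subtraction of free RNA leaves 5 matrix and 6 interferon response genes higher and 3 cholesterol synthesis genes lower. Col1a1 stood at 27.1 CPM in thin limb-like cells, beside 32.2 in macrophage-like cells. Free RNA of fibroblasts may thus enter the matrix list.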

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

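In several gene lists a main class had at least 3 members higher and 0 lower, while another had at least 3 lower and 0 higher at the same time. Lists with members in both directions in a class, such as hypoxia and glycolysis at day 2 in thick ascending limb-like cells, were not picked. None of these differences between classes was tested, since each rests on 1 library per group. The rule that picked them was fixed in advance, but the classes were named and merged after the clusters had been seen.

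At day 2, heat shock genes were higher in 3 of 11 measured in thick ascending limb-like cells and lower in 3 of 10 in thin limb-like cells, or in 2 of 9 without the defining Cryab. The median of the full list stood at percentiles 33.1 and 2.44 of random lists of the same level. At day 7, genes of the unfolded protein response, which helps the endoplasmic reticulum fold proteins, were higher in 6 of 15 in proximal tubule-like and in 4 of 15 in thick ascending limb-like cells, and lower in 3 of 16 in thin limb-like cells (Xbp1, 104 against 219 CPM). The median difference of that list stood at percentiles 78.7, 73.6 and 71.7 of random lists in these classes, so it hardly differs from genes of the same level in any of them, and the contrast may only follow all genes. Under median scaling no gene of that list is higher in proximal tubule-like cells, and 1 is higher and 1 lower in thick ascending limb-like cells. Immediate-early genes at day 7 were higher in 14 of 14 in proximal tubule-like and in 12 of 14 in thick ascending limb-like cells, and lower in 3 of 14 in thin limb-like cells (Btg2, 349 against 1078 CPM). At day 30, cholesterol synthesis genes were higher in 3 of 10 in proximal tubule-like cells and lower in 5 of 11 in thin limb-like cells (Sqle, 33.2 against 68.2 CPM). The median of that list stood at percentiles 62.7 and 0.1. Under median scaling the proximal tubule-like count becomes 0 higher and 3 lower, and without the injured cluster 1 higher.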

How the results depend on the processing

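No paired analysis was possible because each group is a single library and the labels name no animal shared between groups. Nothing here measures spread between animals, and the untreated library differs from the others in depth, mitochondrial share and doublet calling. The settings below that are marked as added were chosen after the data were seen; the cause of each shift was not tested. A minimum of 1000 UMIs left every value unchanged because no library has a cell below it.

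With at most 25% mitochondrial UMIs, the haematopoietic share was 1.80% untreated and 68.9% at day 2, and Clu over all cells was 8.91-, 5.02- and 2.43-fold the untreated level at days 2, 7 and 30. With no mitochondrial limit (added), the shares were 1.03 and 65.2% and the Clu ratios 12.7, 7.06 and 3.38. CPM without mitochondrial genes (added) gave Clu ratios of 9.07, 5.02 and 2.43. With doublets kept, the haematopoietic share was 65.4% at day 2 and 34.6% at day 30. With untreated doublets called at a fixed score (added), the Clu ratios were 10.8, 6.02 and 2.90. Leiden resolution 0.5 gave a haematopoietic share of 39.3% at day 30. Each library clustered alone gave shares of 64.8% at day 2 and 39.4% at day 30, and in proximal tubule-like cells at day 30 it left 17 injury genes higher and 6 transport genes lower. The common floor of UMIs (added) gave haematopoietic shares of 0.166% untreated, 49.3% at day 2 and 30.9% at day 30, Clu ratios of 37.3, 13.8 and 6.63, and kept 62.5% of the genes named by rank.

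Median-ratio scaling gave Clu ratios of 4.60 at day 7 and 2.20 at day 30, and the mean of each cell's CPM gave 7.89 at day 2 and 2.72 at day 30. The share of cells with a Clu UMI was 28.1, 78.2, 97.7 and 72.1% in time order without thinning, and 11.3, 31.5, 39.1 and 25.7% when cells were thinned to 1000 UMIs; by construction, fewer UMIs per cell leave fewer cells with a Clu UMI. A pseudocount of 1 CPM kept 48.9% of the genes named by rank, and subtraction of free RNA (added) 51.1%. Proximal tubule-like cells without the injured cluster (added) had 13 injury genes higher at day 2 and 14 at day 30, and 8 and 6 transport genes lower; 40.0% of the genes by rank were kept. At day 7 that class had 48 cells and gave no value, and neither did classes below 50 cells at the common floor.

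Of 151 named gene values, 1 changed sign with the 25% mitochondrial limit, 1 with median-ratio scaling, 1 with the mean of CPM and 4 with free RNA subtracted. Havcr1 in thick ascending limb-like cells at day 30, with a log2 difference of 0.10, turned to -0.18, -0.0304, -0.0755 and -0.38 in that order of settings. With free RNA subtracted, Havcr1 turned from 1.91 to -0.38 in thick ascending limb-like cells at day 7 and from 2.17 to -1.41 in thin limb-like cells at day 7, and Clu from 2.39 to -1.19 in thin limb-like cells at day 2. Of 206 list values, the larger of the higher and lower counts turned in 17 with free RNA subtracted, 5 with median-ratio scaling and 4 with each library clustered alone. It turned in 3 of 92 at the common floor of UMIs, in 3 of 46 without the injured cluster and in at most 2 of 206 under any other setting.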

Other observations

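Principal cell-like cells of the collecting duct, a type that fine-tunes water and sodium balance, were compared at all 3 times (497 untreated cells against 386, 52 and 210). Injury genes were higher in 15 of 22, 17 of 24 and 17 of 25 measured, and failed-repair genes in 7 of 10, 14 of 15 and 16 of 17. Interferon response genes were higher in 8 of 10, 10 of 11 and 18 of 18, and matrix genes in 4 of 11, 7 of 14 and 17 of 22. Among transport genes of the distal nephron and collecting duct that do not define clusters, 8 of 14, 11 of 14 and 8 of 15 were lower. Aqp2, Aqp3 and Scnn1b define clusters and are not counted. Without them the list still holds genes of intercalated cells (Atp6v1g3, Slc4a1, Foxi1) and of the distal convoluted tubule (Slc12a3, Pvalb). Intercalated-like cells held 12.9% of untreated cells and 1.38, 1.09 and 1.71% later. Less free RNA of other segments may thus enter these lower counts, which do not show a loss of principal cell transport. Oxidative phosphorylation genes were lower in 9, 10 and 11 of 20. Of all measured genes in the class, 8.58, 10.7 and 12.2% were higher and 8.06, 8.20 and 6.37% lower. The class lies mostly in cluster 22 untreated (98.4%) and in cluster 19 later (98.7, 98.1 and 67.1%). Beside 7 markers of its own class, the top 10 genes of cluster 22 hold 3 of the distal convoluted or connecting tubule. These are Calb1, S100g and Scnn1b, the last also a principal cell marker. The top 10 genes of cluster 19 hold Trpv5 of the connecting tubule. Connecting tubule cells are thus not excluded, and differences in this class may in part be between cell types. Median scaling shifts its log2 differences by -0.21 at days 7 and 30, and neither other settings nor subtraction of free RNA were run on its list counts. Lyz2 stood at 205 (day 2), 484 and 581 CPM against 4.88 in these cells. Tyrobp stood at 164, 58.0 and 81.3 CPM against 1.81. Free RNA of haematopoietic cells is thus not excluded as a part of the interferon and matrix differences. Col1a1 stood at 24.4 CPM at day 30, beside 32.2 in macrophage-like cells. Free RNA of fibroblasts is thus not excluded for the matrix list either.

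Technical accounts of 3 patterns were weighed; the tests on Clu in shallow cells and on Cd74 were written after the values had been seen, the others before. The design holds no test of a biological explanation for any of them.

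Haematopoietic cells were few at day 7 (18.2%) beside day 2 and day 30. For neutrophil-like cells, the high UMI floor of the day 7 library could account for their absence: only 3 of 988 day 2 cells above that floor, 0.304% (0.0627 to 0.885), were neutrophil-like. For all haematopoietic cells this stays open: their day 30 share was 19.8 percentage points greater than that at day 7 over all cells and 12.7 (8.31 to 17.2, by normal approximation over cells) above the same floor, and 2 single libraries cannot tell the floor from other differences between them.

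Clu was low in untreated proximal tubule-like cells, although the sort should have taken cells with an active reporter. Its ratio to the level in pericyte-like cells, 0.701 (0.434 to 1.21), leaves open whether shallow cells at background level account for this. Without the barcodes above the fixed doublet score the level was 22.0 instead of 22.7 CPM, a ratio of 1.03, which decides nothing, as doublets with Clu-rich cells would raise the level.

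Cd74, the invariant chain of MHC class II, was higher in tubule classes after ischemia, and free RNA from haematopoietic cells could produce this. In proximal tubule-like cells the Cd74 level was 68.7% of its library mean at day 7 and 27.8% at day 30, against medians of 14.6 and 9.27% for 6 haematopoietic genes, ratios of 4.71 (4.66 to 4.77) and 3.00 (2.95 to 3.05), more than free RNA in 1 ratio would give; at day 2 the ratio of 1.89 (1.69 to 2.10) leaves it open. Subtraction of 30% of the library mean nevertheless ends the day 2 and day 30 calls, since 11.7 and 27.8% lie below it. In thick ascending limb-like cells the ratio was 0.875, 0.922 and 1.07 (1.03 to 1.10) at days 2, 7 and 30, and in thin limb-like cells 1.16 and 1.63 (1.59 to 1.67) at days 7 and 30, within what free RNA may give, while 0.540 (0.398 to 0.716) at day 2 decides nothing. Doublets with antigen-presenting cells, as the only source, would put most Cd74 in few proximal tubule-like cells. The 10% of cells with the most held 36.6% of its UMIs at day 7 and 39.3% at day 30. However, 99.6 and 99.5% of these cells had a Cd74 UMI, and an even base such as free RNA would lower the part held by doublets. Doublets are thus not excluded as a share of the level.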
